A study of Mus musculus with 26 samples.

How the data were processed

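Polyadenylated RNA was measured in 26 libraries of sorted mouse regulatory T cells (Tregs). Per the labels' protocols, cells were sorted into lysis buffer and amplified with Smart-seq2, and libraries were made with the Nextera kit. Smart-seq2 carries no molecular identifiers, so read counts are not independent molecules and every statement on depth covers counting error only. The mice carried the FSF-KrasG12D and p53frt/frt alleles and Foxp3YFP/Cre, per the labels. Genotype (WT, or Fl for Il1rl1fl/fl) and sorted population (DN, SP or DP) came from the labels, which do not name the tissue. All 26 columns of per-sample values were mapped, and 0 were left unused.

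The expected counts per gene symbol were made by the authors with RSEM 1.2.12 and Bowtie 1.0.1 on genome build mm9, per the submitters' processing notes. Gene models, strand setting and filters are not stated there. Because the supplied annotation is of another build, genes are given by symbol and without coordinates. The deposited count table holds 23224 genes. A second deposited table holds normalized signal values for 22484 genes. In each library these values, checked on the files, were the estimated counts of the authors' first table times 1000 divided by 1 constant. Within a library the ratio of both tables varied by at most 9.93e-15. Of the 740 genes missing from the second table, 738 carried microRNA, snoRNA or scaRNA symbols. Calendar dates stood as names of 25 genes, and 16 of these were tested under the name given. A further 3943 genes had no count in any library.

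Total counts ran from 727723 to 6288464 per library. The 5 lowest totals, 727723 to 962563 counts, were those of Fl DN 7833, Fl DN 7859, WT SP 7853, Fl SP 7833 and WT DP 7853. The ribosomal transcript Rn45s took 13.1% to 22.5% of the counts and stayed in the table. No 2 libraries of a group were copies of each other: over 45 pairs, the smallest chi-square per degree of freedom was 8.45.

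Counts were rounded and analysed in R 4.3.3. The filterByExpr function of edgeR 4.0.16 (minimum count 10, minimum total 15) kept 11496 genes. Libraries were scaled with TMM factors. A single edgeR quasi-likelihood model of the 6 groups (prior degrees of freedom 6.98) gave the population comparisons within each genotype, the genotype comparisons within each population, and the genotype difference of each population comparison. Fl against WT averaged over the populations was tested with limma 3.58.1 voom, with the number that opens each title as a random block (consensus correlation 0.0591). Genes with a Benjamini-Hochberg adjusted p under 0.05 passed, and all adjusted p values are from these edgeR and limma fits or from camera. Errors of log2 fold changes are standard errors (SE). For edgeR they were derived from the test, as the absolute change divided by the square root of its F statistic. Levels are depth-scaled counts (CPM) with standard deviations (SD), and log2 CPM used a prior count of 2. Where all libraries of a group had 0 counts, a gene's fold was set to a bound of 3 counts over the group, and list medians are given with those bounds where they differ.

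The 23 gene lists (16 processes and 7 sets of cell type markers) and the rule for naming genes were fixed before the data were examined, as were all comparisons and tests except where stated. The processes were Treg core, tissue Treg and ST2-associated, suppressive effectors, activation and checkpoint receptors, naive and central, chemokine receptors and integrins, Th1, Th2, Th17, Tfr, proliferation, NF-kB targets, interferon response, immediate early and heat shock, glycolysis, and cholesterol and lipid. Markers covered macrophages and dendritic cells, neutrophils, B cells, CD8 T and NK cells, lung epithelium and tumour, endothelium and stroma, and erythrocytes. Some lists share members and are not independent. Fgl2, Il10 and Areg are in the tissue Treg and suppressive lists, and Tnfrsf9 is in the tissue Treg and activation lists. Ctla4 is in the Treg core, suppressive and activation lists. Lag3 is in the suppressive and activation lists, and Tnfrsf4 and Tnfrsf18 are in the Treg core and activation lists. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the estimated correlation. Il1rl1 and the sort markers Itgae and Klrg1 were always named. Among genes that passed and averaged at least 3 log2 CPM, the 12 with the largest rise and the 12 with the largest fall were named (5 each in the Fl population comparisons and the genotype differences). Predicted genes, clone names and antigen receptor segments were left out. Where no gene passed, the 3 smallest p values in each direction were named as values. List members with the smallest p could be named too.

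The numbers that open the titles recur across populations of 1 genotype and were read as mouse numbers, although the labels do not say so. They are 7853, 7854, 7934 and 7955 in WT and 7833, 7859, 7863, 7876 and 8000 in Fl. As a check, deviations from the group means were correlated over 11496 genes: 24 of 25 pairs with 1 number had a positive correlation and 0 were over 0.1 (median 0.0423, against -0.0136 for 90 other pairs). Over the 2648 genes averaging 6 log2 CPM or more, 25 of 25 were positive and 20 were over 0.1 (median 0.155, against -0.0468). Results with this number as a block are given beside a result where they change a call or move a count by over 1.5 times.

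Il1rl1, Itgae, Klrg1 and Foxp3 were also compared between genotypes with 2-sided exact permutation tests of mean log2 CPM, adjusted over the 3 populations. The alternatives were DESeq2 1.42.0, voom with quality weights, other scalings, no filter on low counts, limma-trend on the normalized table, only the libraries compared, the number of genes detected as a covariate, the block, and leaving out each library. Chosen after seeing the data were leaving out Rn45s, the 5 libraries of lowest total, or the macrophage-rich libraries WT DP 7934 and Fl DP 7863, list tests without each library (each title number for the average), and a covariate for sample sheet (S) numbers above 20. The same tests were run on counts simulated for 11496 genes with known changes at 1, 2 and 3 log2 units. Those counts held no mouse effect, no S number difference and no macrophage-rich libraries, so the shares need not hold for the real data. In DP against DN in WT they recovered 5.97%, 37.3% and 47.0% of the changed genes, with 2 unchanged genes among 62 calls. For Fl against WT in DP the shares were 8.96%, 35.8% and 74.2%, with 4 unchanged among 83 calls. For the genotype difference in DP against DN they were 0%, 16.4% and 40.9%, with 3 unchanged among 41 calls. For the average over populations they were 28.4%, 68.7% and 65.2%, with 13 unchanged among 121 calls, which is above the nominal 5 percent. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.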

Results

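Tregs from mice bearing inducible Kras and p53 tumour alleles were sorted by the surface proteins CD103 (encoded by Itgae) and KLRG1 into CD103-KLRG1- (DN), CD103+KLRG1- (SP) and CD103+KLRG1+ (DP) cells. WT mice had intact Il1rl1, which encodes ST2, the receptor for the alarmin IL-33. Fl mice had a floxed Il1rl1 and Foxp3-driven Cre, which deletes floxed DNA in Tregs. The WT groups held 4 DN, 3 SP and 4 DP libraries, and each Fl group held 5. Total counts per library were 1377590 to 3741108 in WT DN, 885180 to 2983546 in WT SP and 962563 to 2141431 in WT DP. They were 727723 to 5776301 in Fl DN, 891305 to 4813988 in Fl SP and 1390238 to 6288464 in Fl DP. On average 11188 to 11495 genes per library had a count, by group.

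Il1rl1 RNA was lower in Fl than in WT Tregs of the SP and DP populations. In SP it averaged 86.5 ± 17.7 CPM (SD, n = 5) in Fl against 350 ± 147 CPM (n = 3) in WT, which is 24.7% of the WT level (exact permutation p = 0.0179, the smallest the design allows; adjusted 0.0268). In DP it averaged 358 ± 125.9 CPM (n = 5) against 988 ± 282 CPM (n = 4), or 36.3% (exact permutation p = 0.0159; adjusted 0.0268). In both populations 5 of 5 Fl libraries lay below the lowest WT library. In DN the means were 77.8 ± 58.8 CPM in Fl and 127 ± 75.6 CPM in WT (exact permutation p = 0.19). The Fl DN libraries 7833, 7859, 7863, 7876 and 8000 held 58.0, 41.5, 43.4, 64.9 and 182 CPM of Il1rl1. The WT DN libraries 7853, 7854, 7934 and 7955 held 240, 105, 84.1 and 80.9 CPM. The Fl SP libraries held 66.5, 91.7, 83.7, 77.2 and 113 CPM in the same order, and WT SP 7853, 7934 and 7955 held 402, 463 and 184 CPM. Fl DP libraries held 399, 544, 242, 363 and 242 CPM, and WT DP libraries held 1056, 1359, 751 and 786 CPM. These are counts over the whole gene, and the labels do not say which exons were floxed. The remaining reads therefore do not measure how completely Il1rl1 was deleted.

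The sort markers followed the sort. Itgae averaged 22.2 ± 6.50 CPM in WT DN and 42.8 ± 46.4 CPM in Fl DN, against 1066 to 1173 CPM in SP and DP of both genotypes. Klrg1 averaged 588 ± 165 CPM in WT DP and 546 ± 86.9 CPM in Fl DP, and 4.51 to 15.2 CPM in the other groups. Neither Itgae nor Klrg1 differed between genotypes in any population (smallest exact permutation p = 0.179). Foxp3, the lineage transcription factor of Tregs, was higher in Fl than in WT DP cells, at 300 ± 52.9 against 205 ± 14.4 CPM (146% of WT, exact permutation p = 0.0159, adjusted 0.0476). In the edgeR model the Foxp3 difference of 0.55 ± 0.21 log2 units did not pass over all genes.

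**Figure D1:**
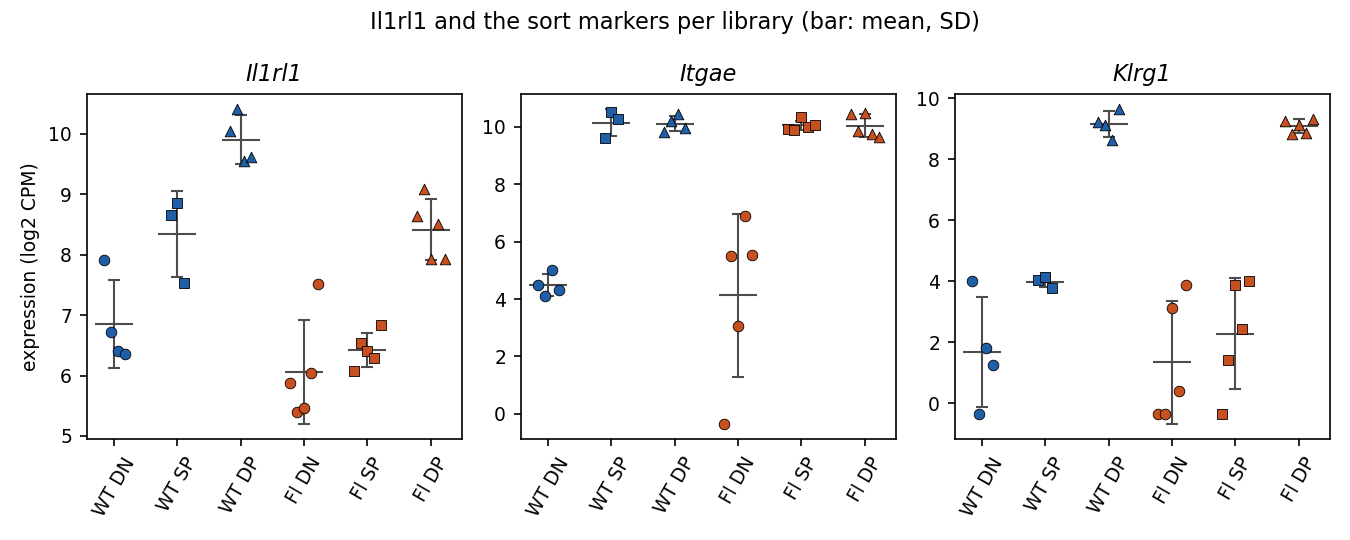
Expression of Il1rl1, Itgae and Klrg1 (log2 CPM, y axis) in each library, by genotype and sorted population (x axis). Points are libraries and bars are the mean and SD; Il1rl1 was lower in 5 of 5 Fl libraries than in any WT library in SP and DP, while Itgae and Klrg1 separated the sorted populations in both genotypes.

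How do the sorted populations differ when IL-33 signalling is intact? WT DP cells had 7.80-fold more Il1rl1 RNA than WT DN cells (log2 2.96 ± 0.43 SE, n = 4 and 4, adjusted p = 0.000356). The high-affinity IL-2 receptor chain Il2ra was 5.15-fold higher (2.36 ± 0.26, adjusted p = 3.95e-06), and the suppressive effector Fgl2 was 4.90-fold higher (2.29 ± 0.24, adjusted p = 3.05e-06). Tcf7, a transcription factor of naive and memory T cells, was 9.01-fold lower (-3.17 ± 0.55, adjusted p = 0.005), and the SAP-binding receptor Slamf6 was 4.69-fold lower (-2.23 ± 0.27, adjusted p = 2.12e-05). The sort markers Klrg1 (145-fold) and Itgae (50.4-fold) passed as well, which checks the labels. Of 11496 genes tested with edgeR, 25 were higher and 25 lower in DP.

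Further named genes rose in WT DP cells. Pcyt1a, an enzyme of phosphatidylcholine synthesis, rose by 3.43 ± 0.66 log2 units, and the leukotriene B4 receptor Ltb4r1 by 2.50 ± 0.56. The protease inhibitor homologue Ctla2a rose by 2.09 ± 0.40, the inhibitory receptor Lilrb4 by 1.96 ± 0.36 and the G protein regulator Rgs2 by 1.81 ± 0.40. The chemokine receptor Cxcr6 rose by 1.79 ± 0.39 and the mitochondrial thiamine pyrophosphate carrier Slc25a19 by 1.68 ± 0.31. Adjusted p values of these 7 genes were 0.00802 to 0.0343. Among the named genes lower in DP, the sialyltransferase St8sia1 changed most, at -5.43 ± 0.99 log2 units (43.3-fold), followed by Tbc1d4, a regulator of glucose transporter traffic, at -4.74 ± 0.74 (26.7-fold). The growth factor receptor Igf1r fell by 2.98 ± 0.56 log2 units, the kinase Map4k4 fell by 2.58 ± 0.54 and Gramd3 changed by -2.26 ± 0.50. A second sialyltransferase, St6gal1, fell by 2.06 ± 0.48, the adhesion molecule Pecam1 by 2.01 ± 0.44 and Ms4a4b by 1.82 ± 0.37. The adaptors Lax1 and Sh2d1a fell by 1.79 ± 0.42 and 1.73 ± 0.33. These 10 genes had adjusted p values of 0.00132 to 0.0483.

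The tissue Treg and ST2-associated genes rose together in WT DP cells: 14 of 14 had positive changes, with a median of 1.46 log2 units (camera adjusted p = 3.24e-17, and 2.54e-07 with an estimated correlation). Of these, 4 passed over all genes and 9 when adjusted over the list alone. Gata3, a transcription factor of type 2 immunity, rose by 1.17 ± 0.21 (adjusted p = 0.00535) and the chemokine receptor Ccr8 by 1.39 ± 0.25 (adjusted p = 0.00665). Il10, an anti-inflammatory cytokine, had a change of 4.16 ± 1.14 and the costimulatory receptor Tnfrsf9 of 1.58 ± 0.45, and neither passed over all genes (adjusted p = 0.128 and 0.163). Il1rl1 and Fgl2 are members of this list. The Th2 list, which shares Gata3 and Il1rl1 with it, also rose (2 of 4 tested members passed; adjusted p = 0.000302, and 0.00551 with an estimated correlation).

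Activation and checkpoint receptors had positive changes for 12 of 14 members (median 0.64; adjusted p = 3.69e-08, and 0.00071 with an estimated correlation). Cd44, a receptor of antigen-experienced T cells, passed over all genes (1.14 ± 0.26, adjusted p = 0.0473), while 9 members were higher and 1 lower when adjusted over the list alone. Suppressive effectors were positive for 10 of 11 members (median 0.92; adjusted p = 5.36e-05, and 0.00482 with an estimated correlation), with 1 passing, Fgl2, and 3 when adjusted over the list alone. The Treg core list passed in the upward direction (adjusted p = 0.00349, and 0.0213 with an estimated correlation), although its mean change of -0.00 and median of 0.43 differ. Il2ra passed upward and Folr4, the folate receptor 4 gene, passed downward (-1.36 ± 0.22, adjusted p = 0.00142), with 5 members higher and 1 lower when adjusted over the list alone. NF-kB targets had a median of 0.38 (adjusted p = 0.0369, but 0.124 with an estimated correlation), with Nfkbid passing (1.63 ± 0.38, adjusted p = 0.0483) and 3 members when adjusted over the list alone. The NF-kB list did not pass without the macrophage-rich libraries WT DP 7934 and Fl DP 7863 (adjusted p = 0.0634).

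Naive and central genes fell together in WT DP cells: 12 of 14 had negative changes, with a median of -1.84 (adjusted p = 3.68e-07, and 0.000128 with an estimated correlation). Tcf7 and S1pr1, the receptor for lymphoid tissue egress, passed over all genes (S1pr1 -1.47 ± 0.34, adjusted p = 0.0473), and 9 members did when adjusted over the list alone. The lymph node homing genes Ccr7 and Sell had changes of -3.59 ± 0.86 and -2.76 ± 0.79 (adjusted p = 0.0594 and 0.163). Th1 genes were lower as a list (median -0.84; adjusted p = 0.00331, and 0.0213 with an estimated correlation, or with it 0.0749 in the blocked model and 0.07 without the 5 libraries of lowest total). Within it Cxcr3, a Th1 chemokine receptor, fell by 1.42 ± 0.27 and the IL-18 receptor chain Il18r1 by 1.42 ± 0.29 log2 units (adjusted p = 0.00891 and 0.0143), and 4 members passed when adjusted over the list alone. The Tfr (follicular regulatory) list was lower too (adjusted p = 0.0314, and 0.0485 with an estimated correlation), with Sh2d1a passing and 2 members when adjusted over the list alone. Its call was lost in the blocked model (adjusted p = 0.0518) and without the macrophage-rich libraries (adjusted p = 0.116), and without the 5 libraries of lowest total it gave 0.0737 with an estimated correlation.

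Marker lists of other cell types differed between the populations in WT. Summed macrophage and dendritic cell markers were 1251 ± 1649 CPM in WT DP against 402 ± 199 CPM in WT DN. Of 13 markers tested, 12 had positive changes (median 4.83, or 4.31 with bounds; adjusted p = 5.36e-05, but 0.151 with an estimated correlation). None passed over all genes in edgeR, and 5 did when adjusted over the list alone. Without WT DP 7934 and Fl DP 7863 this list did not pass (adjusted p = 0.176). Lung epithelium markers were 75.9 against 34.9 CPM (median 3.52, or 2.30 with bounds; adjusted p = 0.0255, and 0.0485 with an estimated correlation, or with it 0.0803 in the blocked model, 0.0894 without the macrophage-rich libraries and 0.0737 without the 5 libraries of lowest total). CD8 T and NK cell markers were 36.6 ± 8.88 against 11.1 ± 5.95 CPM (median 3.49, or 1.87 with bounds; adjusted p = 0.0485, but 0.151 with an estimated correlation, 0.068 in the blocked model and 0.0817 without the 5 libraries of lowest total). Endothelial markers were lower, at 28.5 against 97.6 CPM, with Pecam1 the only member tested (adjusted p = 0.025, and 0.0485 with an estimated correlation, but 0.207 without the 5 libraries of lowest total, or 0.0639 in the blocked model with an estimated correlation).

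With the title number as a block, 115 genes passed in DP against DN in WT, 49 of them among the 50 above. Quality weights gave 93 and DESeq2 143, and 23 passed without the 5 libraries of lowest total. Leaving out WT DN 7853, WT DP 7854 or WT DP 7955 gave 31, 28 or 27 genes. Of the 24 genes named, Ltb4r1, Ctla2a, Rgs2, Cxcr6, Igf1r, Map4k4, Gramd3, St6gal1, Pecam1, Ms4a4b and Lax1 lost their call without at least 1 of the 8 libraries, with the highest adjusted p for Lax1, DP vs DN in WT (0.197 without WT DP 7955). Of the lists, tissue Treg, suppressive, activation, naive, Th1 and Th2 genes held without any 1 library, also with an estimated correlation. Treg core genes held at the preset correlation (0.0729 with an estimated correlation without WT DN 7854). The NF-kB, Tfr, macrophage, CD8 T and NK, lung and endothelial lists each lost their call without at least 1 library (adjusted p up to 0.0924, 0.0835, 0.204, 0.139, 0.107 and 0.415).

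**Figure D2:**
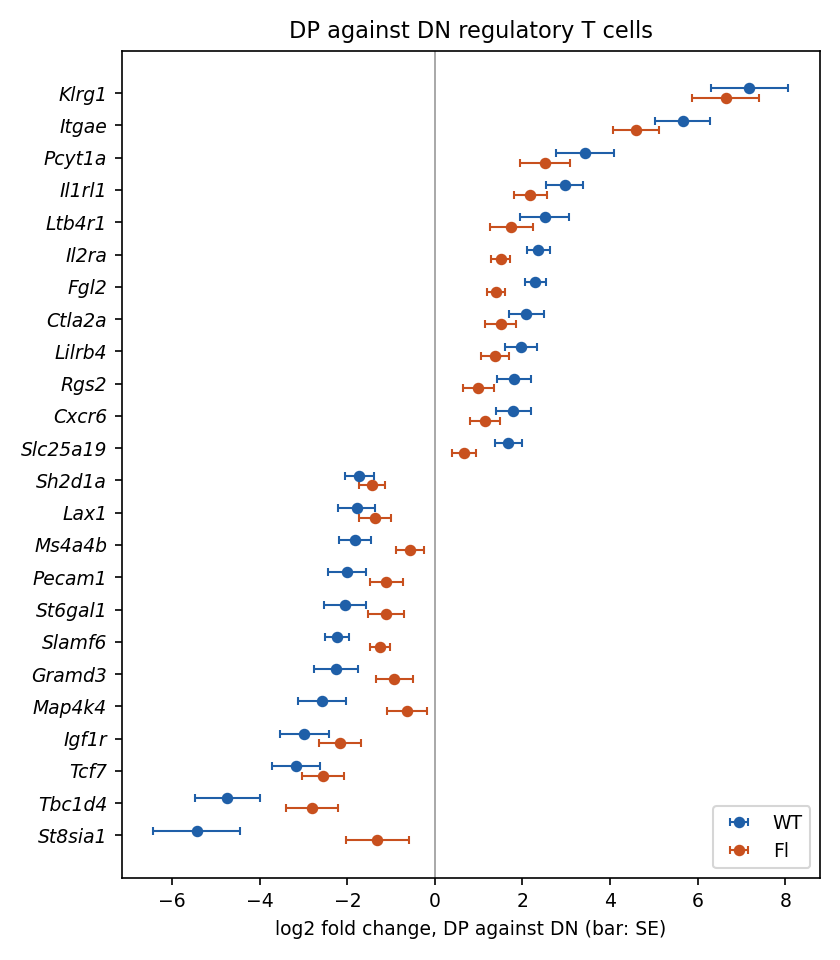
Log2 fold change of DP against DN (x axis) for the 24 genes named in WT (y axis), with WT and Fl side by side. Points are edgeR estimates and bars are standard errors; Il1rl1, Il2ra and Fgl2 were positive and Tcf7 and Slamf6 negative in both genotypes.

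SP cells of WT mice, which bear CD103 without KLRG1, differed less from DN cells. Itgae was 52.6-fold higher (5.72 ± 0.63, n = 3 and 4, adjusted p = 1.40e-05) and Fgl2 was 2.76-fold higher (1.46 ± 0.24, adjusted p = 0.0117). These were the 2 genes that passed. Il1rl1 had a change of 1.46 ± 0.43 (adjusted p = 0.848) and Klrg1 of 1.91 ± 0.87 (adjusted p = 0.868). Tissue Treg genes rose as a list (11 positive, median 0.69; adjusted p = 0.00196, and 0.01 with an estimated correlation), with Fgl2 passing and 3 members when adjusted over the list alone. Suppressive effectors rose (9 positive, median 0.64; adjusted p = 0.00196, and 0.0294 with an estimated correlation, or 0.0594 with it without the 5 libraries of lowest total) and naive and central genes fell (11 negative, median -0.89; adjusted p = 0.000307, and 0.00372 with an estimated correlation). NF-kB targets were higher (median 0.31; adjusted p = 0.0181, but 0.105 with an estimated correlation), as was the Th2 list (adjusted p = 0.0274, but 0.105 with an estimated correlation, and 0.267 without the 5 libraries of lowest total). Treg core and activation genes did not pass (adjusted p = 0.0608 and 0.0984), except in the blocked model (0.0395 and 0.0161, but 0.0988 and 0.175 with an estimated correlation) and without some single libraries (down to 0.0293 and 0.0336). CD8 T and NK cell markers were 51.3 ± 40.5 CPM in WT SP (median change 0.95, or 3.48 with bounds; adjusted p = 0.0274, but 0.131 with an estimated correlation, and 0.142 without the 5 libraries of lowest total). Fgl2 no longer passed without WT DN 7934, WT SP 7853 or WT SP 7934 (adjusted p = 0.0817, 0.129 and 0.121), which left 1 gene each. For Fgl2, SP vs DN in WT, the call was also lost without the 5 libraries of lowest total (adjusted p = 0.256) and with only the libraries compared (0.681), while DESeq2 called 9 genes. Without WT SP 7934 the tissue Treg and suppressive lists gave 0.0721 and 0.114 with an estimated correlation. The Th2, NF-kB and CD8 T and NK lists lost their call without at least 1 library (adjusted p up to 0.235, 0.622 and 0.273).

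Between DP and SP cells of WT mice, only the sort marker Klrg1 passed (5.27 ± 0.89, adjusted p = 0.0285). Il1rl1 had a change of 1.5 ± 0.45 (adjusted p = 0.698) and Itgae of -0.06 ± 0.54. Tissue Treg genes rose as a list, with 14 of 14 positive (median 0.77; adjusted p = 9.15e-10, and 2.17e-05 with an estimated correlation). None of these passed over all genes in edgeR, and 4 did when adjusted over the list alone. Activation and checkpoint receptors rose (12 positive, median 0.35; adjusted p = 4.41e-05, and 0.0115 with an estimated correlation, or 0.0866 in the blocked model with an estimated correlation). Th1 genes were lower (8 negative, median -0.47; adjusted p = 0.0101, but 0.0597 with an estimated correlation), with Il18r1 at -1.43 ± 0.30 and Cxcr3 at -1.34 ± 0.29 (adjusted p = 0.12 for both). The Th2 list was higher (adjusted p = 0.0306, but 0.0899 with an estimated correlation). Naive and central genes were lower (median -0.78, or -0.87 with bounds; adjusted p = 0.0395, but 0.0845 with an estimated correlation), though not without the macrophage-rich libraries (adjusted p = 0.291) or without the 5 libraries of lowest total (0.0684). The Tfr list passed only in the blocked model (adjusted p = 0.0397, but 0.0955 with an estimated correlation, against 0.0867 without the block). Macrophage markers were higher in DP (adjusted p = 0.0288, but 0.506 with an estimated correlation), though not without WT DP 7934 and Fl DP 7863 (adjusted p = 0.866). For Klrg1, DP vs SP in WT, the adjusted p was 0.0656 to 0.309 without WT SP 7853, WT SP 7934, WT SP 7955, WT DP 7853 or WT DP 7955, and the last 4 of these left 0 genes by edgeR, as did leaving out the macrophage-rich libraries or the 5 of lowest total. In the full edgeR comparison 675 genes had an unadjusted p under 0.05, and DESeq2 called 28. Without WT SP 7955 activation receptors gave 0.0807 with an estimated correlation. The naive, Th2 and macrophage lists lost their call without at least 1 library (adjusted p up to 0.282, 0.152 and 0.892). The macrophage list also turned direction on leaving out 1 library.

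The same comparisons in Fl mice ask whether the populations remain distinct when ST2 is targeted in Tregs. Fl DP cells had 4.52-fold more Il1rl1 RNA than Fl DN cells (2.18 ± 0.37, n = 5 and 5, adjusted p = 0.00554). Il2ra rose by 1.5 ± 0.23 log2 units (adjusted p = 0.00124), Fgl2 by 1.39 ± 0.21 (adjusted p = 0.00116) and Gata3 by 0.94 ± 0.18 (adjusted p = 0.016). The transcription factor Ikzf4 rose by 1.43 ± 0.22 and the costimulatory receptor Tnfrsf18 by 0.73 ± 0.13 (adjusted p = 0.00168 and 0.00697). Tcf7 fell by 2.55 ± 0.48 log2 units, Tbc1d4 by 2.80 ± 0.59, Igf1r by 2.17 ± 0.48, the CD30 ligand gene Tnfsf8 by 2.06 ± 0.40 and the inhibitory receptor Btla by 1.80 ± 0.36 (adjusted p = 0.0116 to 0.0482). Cxcr3 fell by 1.41 ± 0.24 and Sh2d1a by 1.43 ± 0.29 (adjusted p = 0.00554 and 0.0253). The transporter Abcc10 and C87436 rose by 3.29 ± 0.73 and 2.97 ± 0.63 (adjusted p = 0.0482 and 0.0373). With the sort markers Klrg1 (6.64 ± 0.76) and Itgae (4.58 ± 0.52), 16 genes were higher and 11 lower in edgeR.

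Treg core genes rose in Fl DP cells (10 positive, median 0.46; adjusted p = 7.45e-08, and 0.000265 with an estimated correlation), with 3 passing over all genes and, adjusted over the list alone, 7 higher and 1 lower. Tissue Treg genes rose (13 of 14 positive, median 0.97; adjusted p = 2.18e-08, and 6.12e-05 with an estimated correlation), with 3 passing and 5 when adjusted over the list alone. Activation and checkpoint receptors rose (11 positive, median 0.33; adjusted p = 0.000515, and 0.0162 with an estimated correlation), as did the Th2 list (adjusted p = 0.000262, and 0.00474 with an estimated correlation). Naive and central genes fell (12 negative, median -0.73; adjusted p = 0.00119, and 0.00573 with an estimated correlation). Th1 genes fell (8 negative, median -0.37; adjusted p = 0.00446, and 0.0319 with an estimated correlation, or 0.0909 with it without the 5 libraries of lowest total), and so did Tfr genes (median -1.43; adjusted p = 0.000515, and 0.00474 with an estimated correlation). Macrophage markers summed to 1299 ± 2097 CPM in Fl DP against 338 ± 71.4 CPM in Fl DN, with 13 of 13 positive (median 4.29, or 2.88 with bounds; adjusted p = 0.000515, but 0.263 with an estimated correlation). That list did not pass without WT DP 7934 and Fl DP 7863 (adjusted p = 0.0626). Summed endothelial markers were 48.1 CPM in Fl DP against 105 ± 32.4 CPM in Fl DN. Again only Pecam1 was tested, which does not measure endothelial cells (camera adjusted p = 0.0389, but 0.0832 with an estimated correlation, 0.122 without the macrophage-rich libraries and 0.416 without the 5 libraries of lowest total). Suppressive effectors (adjusted p = 0.206) and NF-kB targets (adjusted p = 0.62) did not pass.

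With the title number as a block, 59 genes passed in DP against DN in Fl, 25 of them among the 27 above; Abcc10 and C87436 did not. DESeq2 called 96 and the S number covariate gave 41. The count was 16 without the macrophage-rich libraries, 17 with only the libraries compared and 7 without the 5 libraries of lowest total, and leaving out Fl DN 7833, Fl DN 7863 or Fl DP 7863 gave 15, 16 or 15. Abcc10, C87436, Tbc1d4, Igf1r, Tnfsf8 and Btla lost their call without at least 1 of the 10 libraries, and Tcf7 did without Fl DP 7863 (for Tcf7, DP vs DN in Fl, adjusted p = 0.0513). Every list above kept its call at the preset correlation without any 1 library, except macrophage markers without Fl DP 7863 (adjusted p = 0.142) and endothelial markers without 7 of the libraries. With an estimated correlation activation and Th1 genes did not always hold (up to 0.0673 and 0.0911).

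Of the 50 genes that passed for DP against DN in WT, 49 changed in the same direction in Fl, 42 had an unadjusted p under 0.05 there, and 16 passed in both genotypes (8 higher, 8 lower), against 0.0587 expected from independent calls. Il1rl1, Il2ra, Fgl2, Gata3, Tcf7, Tbc1d4, Igf1r, Slamf6, Sh2d1a and Cxcr3 were among the 16. So were the sort markers Itgae and Klrg1, which the gate fixes in both genotypes. Both comparisons also come from 1 edgeR model with a shared estimate of each gene's spread. Their calls are therefore not independent, and the expected number is too low a reference. The median absolute change of the 50 genes was 1.70 log2 units in WT, where they were selected, and 0.929 in Fl. Over the 8068 genes averaging 3 log2 CPM or more, the changes in WT and Fl correlated at r = 0.317 (Pearson) and 0.21 (Spearman), across genes, which are not independent replicates. SP lay between DN and DP for 42 of 48 genes (87.5%) that passed in WT and were followed in the Fl libraries, and for 23 of 25 genes (92%) that passed in Fl and were followed in WT libraries. On the first principal component (6.61% of variance) the means were -32.6 ± 10.8, 5.02 ± 27.7 and 42.2 ± 22.8 (SD) in WT DN, SP and DP. In Fl they were -36.0 ± 13.2, 2.68 ± 15.7 and 22.6 ± 8.63. This component did not follow the population alone. WT SP 7853 scored 36.0, against -3.58 and -17.4 in WT SP 7934 and 7955, so the WT SP mean rests largely on it. WT DP 7853 and 7854 scored 67.2 and 55.2, against 27.9 and 18.4 in WT DP 7934 and 7955.

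**Figure D3:**
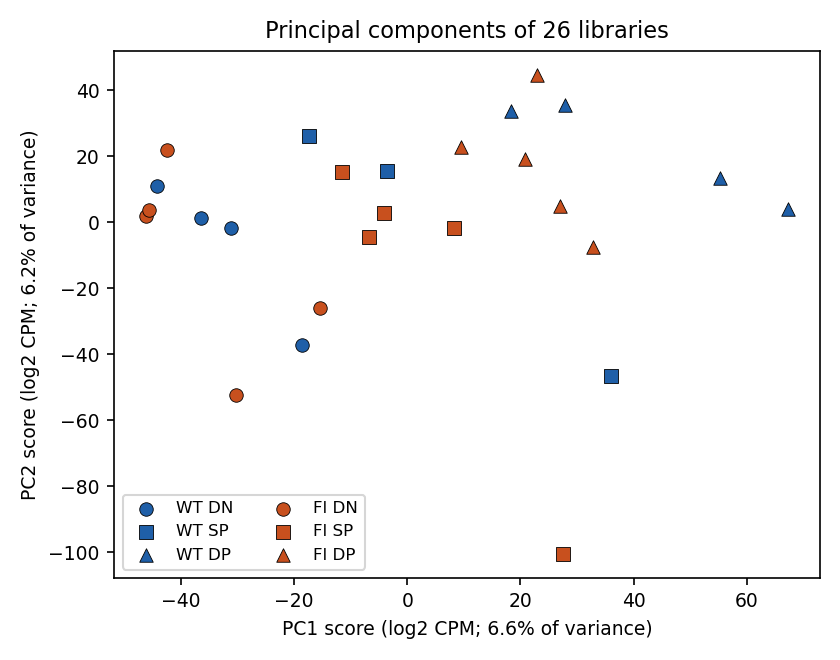
Scores of the 26 libraries on the first (x axis, 6.61% of variance) and second (y axis, 6.23% of variance) principal components of log2 CPM. Color gives the genotype and marker shape the sorted population; DN libraries lie at low and DP libraries at high scores of the first component.

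SP against DN in Fl gave 1 gene, the sort marker Itgae (4.55 ± 0.52, 23.5-fold, n = 5 and 5, adjusted p = 2.97e-05). Il1rl1 had a change of 0.13 ± 0.36 and Klrg1 of 0.60 ± 0.71. Ikzf4 and Fgl2 had changes of 1.14 ± 0.22 and 0.98 ± 0.20 (adjusted p = 0.0813 and 0.146). For Itgae, SP vs DN in Fl, the call was lost with only the libraries compared (adjusted p = 0.069), which left 0 genes, while DESeq2 called 39. Treg core genes rose as a list (10 positive, median 0.38; adjusted p = 0.000505, and 0.0204 with an estimated correlation, or 0.0724 with it without the 5 libraries of lowest total), with 2 members passing when adjusted over the list alone. Tissue Treg genes also rose (11 positive, median 0.58; adjusted p = 0.0045, and 0.0204 with an estimated correlation, or 0.0755 with it without the 5 libraries of lowest total), with 3 higher, and Batf lower, when adjusted over the list alone. B cell markers were higher, at 117 ± 37.8 CPM in Fl SP against 60.2 ± 47.4 CPM in Fl DN (adjusted p = 0.0312, but 0.181 with an estimated correlation, and 0.24 in the blocked model). Summed endothelial markers were lower, at 47.4 CPM, with Pecam1 alone tested (camera adjusted p = 0.0136, but 0.0656 with an estimated correlation, and 0.467 without the 5 libraries of lowest total). Macrophage markers summed to 550 ± 103 CPM in Fl SP against 338 ± 71.4 CPM in Fl DN and did not pass (adjusted p = 0.285), except without WT DP 7934 and Fl DP 7863 (0.00798, but 0.239 with an estimated correlation). With the block 13 genes passed. Without Fl SP 7859, Fl DN 7833 or Fl DN 7876 the count was 4, 2 or 2. Without Fl DN 7876 tissue Treg genes did not pass (adjusted p = 0.0591) and Treg core genes gave 0.0274, but 0.0749 with an estimated correlation. B cell and endothelial markers lost their call without at least 1 library (adjusted p up to 0.186 and 0.29).

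DP cells of Fl mice differed from SP cells in 3 genes. Klrg1 rose by 6.04 ± 0.72 (adjusted p = 6.84e-05) and Il1rl1 by 2.04 ± 0.37 log2 units (adjusted p = 0.0401), while Il18r1 fell by 1.37 ± 0.25 (adjusted p = 0.0401). Itgae had a change of 0.03 ± 0.45. Tissue Treg genes rose (12 positive, median 0.43; adjusted p = 0.00467, and 0.0221 with an estimated correlation), with Il1rl1 passing over all genes and 2 members when adjusted over the list alone. Activation genes were higher (adjusted p = 0.00534, but 0.0967 with an estimated correlation), as were Treg core and Th2 genes (adjusted p = 0.0235 and 0.0358, but 0.0967 for both with an estimated correlation), though Treg core genes did not pass without the macrophage-rich libraries (0.163). Th1 genes and B cell markers were lower (adjusted p = 0.0196 and 0.0172, but 0.0967 for both with an estimated correlation). The Tfr list did not pass (adjusted p = 0.0635), but was lower without Fl SP 7863 (0.00757, and 0.0352 with an estimated correlation) or without Fl DP 7833. Naive and central genes did not pass (adjusted p = 0.0635), except in the blocked model (0.0142) and without the macrophage-rich libraries (0.0393, or 0.0379 without Fl DP 7863 alone), and neither of the first 2 held with an estimated correlation (0.0646 and 0.107). Macrophage markers were higher (adjusted p = 0.035, but 0.578 with an estimated correlation), though not without WT DP 7934 and Fl DP 7863 (adjusted p = 0.482). With the block 8 genes passed. DESeq2 called 26 and limma-trend called 0 on the normalized table. Leaving out Fl SP 8000 gave 6 genes. For Il1rl1, DP vs SP in Fl, the call held without Fl SP 8000, Fl DP 7863 or Fl DP 8000 and was lost without each of the other 7 libraries (adjusted p = 0.0744 to 0.16). Il18r1 kept its call only without Fl SP 8000. Klrg1 alone remained without the macrophage-rich libraries or without Fl SP 7833, Fl SP 7859, Fl SP 7876, Fl DP 7859 or Fl DP 7876. Tissue Treg genes held as a list without any 1 library, though not with an estimated correlation (up to 0.0794). The activation, Treg core, Th1, Th2, B cell and macrophage lists lost their call without at least 1 library (adjusted p up to 0.0882, 0.156, 0.0683, 0.233, 0.065 and 0.963). The macrophage list also turned direction on leaving out 1 library.

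What did targeting Il1rl1 change within each population? In DP cells Nfkbia, which encodes the NF-kB inhibitor IkB-alpha and is itself an NF-kB target, was lower in Fl, at 456 ± 60.1 CPM (SD, n = 5) against 989 ± 220 CPM (n = 4) in WT. The change was -1.12 ± 0.19 log2 units (SE, adjusted p = 0.0271), and Nfkbia was the 1 gene that passed in edgeR (584 had an unadjusted p under 0.05, and DESeq2 called 13). All 5 Fl DP libraries lay below the lowest WT DP library. Nfkbiz, which encodes the related protein IkB-zeta, had a change of -1.56 ± 0.30 (adjusted p = 0.0909). S1pr1 had a change of 1.58 ± 0.33 (adjusted p = 0.2), the interferon-inducible Pyhin1 of 1.14 ± 0.25 (adjusted p = 0.325) and Il1rl1 of -1.46 ± 0.38 (adjusted p = 0.563). For Nfkbia, Fl vs WT in DP, the call held without WT DP 7853 or Fl DP 7859, but not without WT DP 7854, WT DP 7934, WT DP 7955, Fl DP 7833, Fl DP 7863, Fl DP 7876 or Fl DP 8000 (adjusted p = 0.0653 to 0.186), nor without both macrophage-rich libraries (0.204), nor with only the DP libraries in the model (0.0719).

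The tissue Treg list was lower in Fl than in WT DP cells (8 of 14 negative, median -0.06, mean -0.23; adjusted p = 0.00832, and 0.0273 with an estimated correlation). No member passed over all genes in edgeR, and Il1rl1, the targeted gene, passed when adjusted over the list alone (-1.46). The list was not tested without Il1rl1 here, so its call does not show a fall of the other members. Fgl2 had a change of -0.54 ± 0.21, Batf of -0.72 ± 0.28 and Ccr8 of -0.48 ± 0.23. Without the macrophage-rich libraries the adjusted p was 0.12 with an estimated correlation, and without the 5 libraries of lowest total it was 0.148; without any 1 library the list passed at the preset correlation, but gave up to 0.146 with an estimated correlation. Activation receptors (12 of 14 negative, median -0.33) and suppressive effectors (median -0.39) were lower (adjusted p = 0.0406 for both, but 0.209 for both with an estimated correlation), and activation receptors did not pass without the 5 libraries of lowest total (0.0819). Glycolysis genes were lower (10 of 15 negative, median -0.22; adjusted p = 0.027, but 0.328 with an estimated correlation). Naive and central genes did not pass with all libraries (adjusted p = 0.0834), with S1pr1 passing when adjusted over the list alone. NF-kB targets (adjusted p = 0.155) and interferon genes (adjusted p = 0.0527) did not pass either. The suppressive, activation and glycolysis lists lost their call without at least 1 library (adjusted p up to 0.236, 0.181 and 0.169).

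In SP cells no gene passed between genotypes with edgeR, where 620 genes had an unadjusted p under 0.05 and DESeq2 called 7. Il1rl1 had the smallest p, with a change of -2.01 ± 0.41 (adjusted p = 0.397), followed among lower genes by Zcchc9 (-1.47 ± 0.34) and Gps1 (-1.19 ± 0.29). Without Fl SP 7859, 1 gene passed. Among higher genes Tiparp (2.68 ± 0.70), Pxk (1.37 ± 0.38) and Crkl (1.36 ± 0.38) had the smallest p. NF-kB targets were lower as a list (9 of 16 negative; adjusted p = 0.046, but 0.265 with an estimated correlation), and Nfkbia (-0.74 ± 0.20) and Nfkbiz (-0.96 ± 0.32) passed when adjusted over the list alone. B cell markers were higher, at 117 ± 37.8 CPM in Fl SP against 45.3 ± 7.73 CPM in WT SP (6 of 6 positive, median 2.59, or 2.15 with bounds; adjusted p = 0.0102, but 0.243 with an estimated correlation). Without WT SP 7955 neither list passed (adjusted p = 0.895 and 0.0727).

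In DN cells no gene passed between genotypes with edgeR, where 553 genes had an unadjusted p under 0.05 and DESeq2 called 8. The smallest p values were those of Abcc10 (-3.89 ± 0.76, adjusted p = 0.257), Fkbp15 (-1.88 ± 0.45) and Oaz2-ps (-0.85 ± 0.22) among lower genes. Among higher genes they were those of the heat shock gene Hsph1 (1.64 ± 0.39), the retinoid X receptor gene Rxra (4.08 ± 0.99) and Chmp2b (1.54 ± 0.42). Il1rl1 had a change of -0.68 ± 0.38. CD8 T and NK cell markers were 41.3 ± 16.0 CPM in Fl DN against 11.1 ± 5.95 CPM in WT DN (median change 6.03, or 2.55 with bounds; adjusted p = 0.0251, but 0.292 with an estimated correlation, 0.578 without the 5 libraries of lowest total and up to 0.305 without 1 library). The other 22 lists had adjusted p values of 0.627 to 0.968.

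Averaged over the 3 populations, 8 genes passed in limma (1 higher and 7 lower in Fl). The count was 2 to 13 on leaving out each title number, and 5 of 56 splits of the title numbers gave as many (highest other 72). Nfkbia fell by 0.80 ± 0.11 log2 units (SE, adjusted p = 0.0012) and Nfkbiz by 1.06 ± 0.17 (adjusted p = 0.00799). The random block used 1 correlation of 0.0591 for all genes. Libraries with 1 title number correlated more over genes averaging 6 log2 CPM or more (median 0.155). The SEs of such genes may therefore understate the spread between mice. Il1rl1 itself fell by 1.27 ± 0.24 and Cd52, a lymphocyte surface glycoprotein, by 0.56 ± 0.11 (adjusted p = 0.0401 for both). Dgat2, an enzyme of triglyceride synthesis, was lower (adjusted p = 0.0401), though libraries without a Dgat2 count make its size uncertain: limma gave an average of -5.38 ± 1.04, beyond each edgeR change of -1.07 ± 1.21, -3.88 ± 1.32 and -2.95 ± 1.21 in DN, SP and DP. The lysosomal protein gene Laptm5 fell by 0.37 ± 0.07 (adjusted p = 0.046). Pyhin1 rose by 0.84 ± 0.17 (adjusted p = 0.0481). The 8th gene was a clone name, 5830416I19Rik. Itgae (0.17 ± 0.40) and Klrg1 (-0.52 ± 0.66) did not pass.

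By population, Nfkbia averaged 443 ± 75.7 CPM in Fl against 642 ± 151 CPM in WT DN cells, and 514 ± 77.5 against 856 ± 257 CPM in SP cells. Nfkbiz averaged 114 ± 26.4 against 185 ± 42.5 CPM in DN, 114 ± 44.0 against 222 ± 60.9 CPM in SP and 125 ± 43.3 against 367 ± 124 CPM in DP. In SP and DP all 5 Fl libraries lay below the lowest WT library for both genes. Dgat2 was read in 3, 2 and 4 of 5 Fl libraries of DN, SP and DP, and averaged 28.3 ± 22.1 CPM in Fl DP against 215 ± 39.0 CPM in WT DP. Pyhin1 averaged 240 ± 66.1 CPM in Fl DP against 109 ± 17.6 CPM in WT DP.

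**Figure D4:**
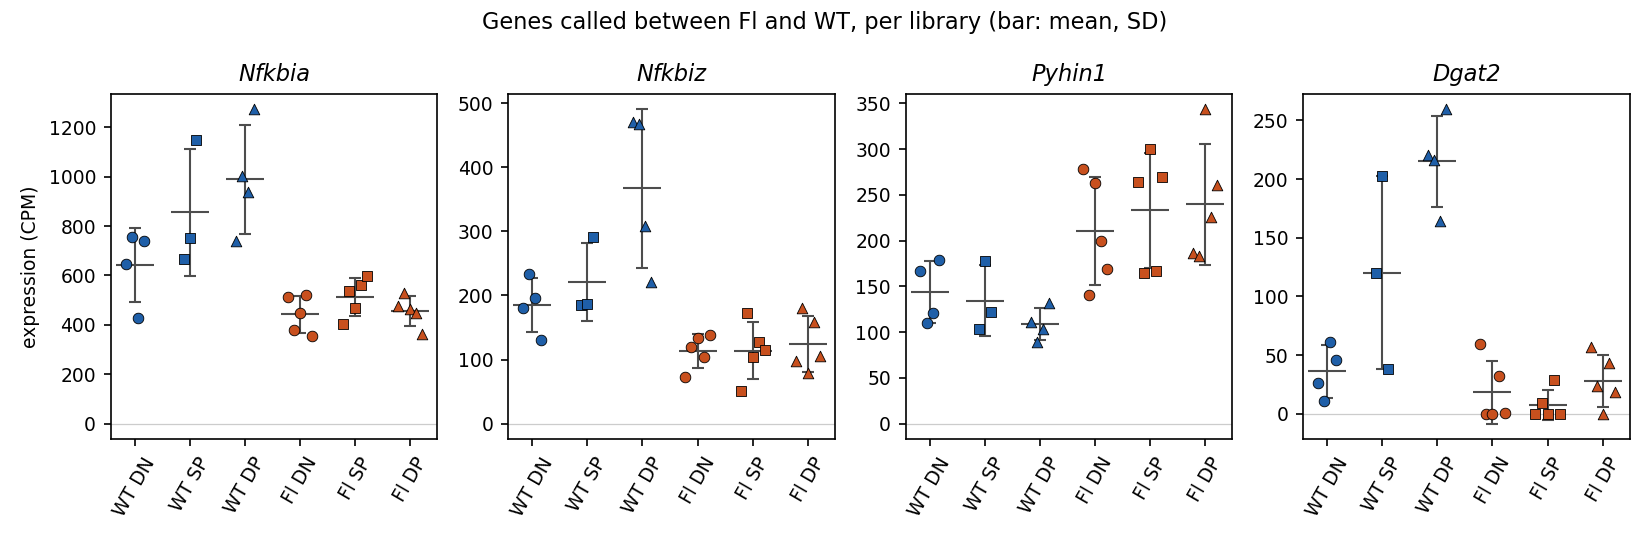
Expression (CPM, y axis) of Nfkbia, Nfkbiz, Pyhin1 and Dgat2 in each library, by genotype and population (x axis). Points are libraries and bars are the mean and SD; Nfkbia and Nfkbiz of all 5 Fl libraries lie below the lowest WT library in SP and in DP.

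The NF-kB target list was lower in Fl on average (11 of 16 negative, median -0.10; adjusted p = 0.0207, but 0.188 with an estimated correlation). Nfkbia and Nfkbiz passed in it. Whether the other 14 targets share the fall was not decided: their median was -0.04 (9 negative; camera p = 0.84 with an estimated correlation, a test chosen after the list's result was seen). B cell markers were higher in Fl (6 of 6 positive, median 1.37; adjusted p = 0.0132, but 0.188 with an estimated correlation). Without the number 7955 neither list passed (adjusted p = 0.407 and 0.234). Tissue Treg, Treg core, suppressive, activation and naive lists did not pass (adjusted p = 0.154 to 0.769).

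Sample sheet numbers split the libraries into 15 with S up to 20 and totals of 2053996 to 6288464 counts, and 11 with S above 20 and totals of 727723 to 2179418 counts. That split was chosen after seeing the data, and each side holds both genotypes. Within the lower S numbers (2 WT and 3 Fl title numbers) and the higher (2 and 2), limma with the random block gave Nfkbia changes of -0.82 ± 0.14 and -0.67 ± 0.14, Nfkbiz of -0.93 and -1.24, and Il1rl1 of -1.08 and -1.76. The changes were -0.65 and -0.38 for Cd52, -6.10 and -3.21 for Dgat2, and 0.84 and 0.81 for Pyhin1. Laptm5 was at -0.41 ± 0.08 and -0.04 ± 0.09. Of these genes only Il1rl1 passed, within the higher numbers (adjusted p = 0.0387). Nfkbia passed in the averaged comparison without any 1 title number. For Nfkbiz, Fl vs WT averaged over DN, SP and DP, the adjusted p was 0.0826 without 7863. The count fell to 2 without 7833, 7853, 7863 or 7934 and rose to 13 without 7859 or 7876. Il1rl1, Cd52, Dgat2, Laptm5 and Pyhin1 each lost their call without at least 1 title number, with the highest adjusted p for Laptm5, Fl vs WT averaged over DN, SP and DP (0.376 without 7955). With quality weights Nfkbia alone passed.

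Does the difference between populations itself depend on genotype? No gene passed with edgeR for SP against DN, DP against DN or DP against SP. Unadjusted p values under 0.05 numbered 564, 494 and 513, and DESeq2 called 5, 7 and 5 genes. The genotype difference of Il1rl1 was -1.33 ± 0.56 for SP against DN, -0.79 ± 0.54 for DP against DN and 0.54 ± 0.56 for DP against SP. For DP against DN, the genotype differences were -0.91 ± 0.30 for Fgl2, -0.87 ± 0.33 for Il2ra and -0.68 ± 0.33 for Ccr8. The smallest p values there were those of Abcc10 (4.45 ± 1.03), Oaz2-ps (1.28 ± 0.32) and Btf3l4 (1.94 ± 0.53) on the positive side. On the negative side they were those of the importin gene Ipo7 (-2.40 ± 0.58), the mitochondrial ribosomal protein gene Mrpl28 (-2.88 ± 0.82) and the snoRNP gene Nhp2 (-2.29 ± 0.66). For SP against DN they were those of Otud4 (2.29 ± 0.54), C87436 (3.53 ± 0.96), Abcc10 (3.79 ± 1.08), Chmp2b (-2.23 ± 0.59), Ampd2 (-2.44 ± 0.68) and Bzw1 (-0.99 ± 0.28). For DP against SP they were those of St8sia1 (4.89 ± 1.2), Agap2 (2.75 ± 0.79), Tcf3 (2.68 ± 0.86), Pja2 (-2.15 ± 0.65), Orc3 (-1.72 ± 0.52) and Tiparp (-2.80 ± 0.87). None of these passed (adjusted p = 0.871 or more).

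As a list, tissue Treg genes rose less from DN to DP in Fl than in WT: 13 of 14 differences were negative, with a median of -0.71 log2 units (adjusted p = 0.0287, but 0.108 with an estimated correlation, and 0.0212 in the blocked model with an estimated correlation). Suppressive effectors showed a median difference of -0.62 (adjusted p = 0.037, but 0.161 with an estimated correlation, and 0.0212 in the blocked model with an estimated correlation). Neither passed without the 5 libraries of lowest total (adjusted p = 0.071 for both), and they lost their call without 4 and 5 of the 18 libraries (up to 0.0898 and 0.12). Naive and central genes, with a median difference of 0.88, did not pass (adjusted p = 0.0536), except in the blocked model (0.0153, but 0.117 with an estimated correlation) and without each of 7 libraries (down to 0.0256, where an estimated correlation gave 0.0793). For SP against DN, suppressive, naive and glycolysis genes passed in the blocked model (adjusted p = 0.0268, 0.0462 and 0.042, but 0.115, 0.128 and 0.115 with an estimated correlation, against 0.202, 0.211 and 0.202), and glycolysis genes without WT SP 7934 too (0.0212, but 0.549 with an estimated correlation).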

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

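The values in this part stood apart from the rest of their group or differed between genotypes. The 3 patterns weighed were chosen after seeing them; the tests of Il1rl1 signalling, of macrophage RNA and of tissue Treg genes within S number sets were set after related results had been seen, and the other tests before their own results were. The gap of the highest and lowest library was tested in the 5 groups of 4 or 5 libraries. WT SP, with 3 libraries, was not tested. Of 85 combinations of 17 measures and these groups, 8 stood apart, where chance gives about 1 in 20.

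The tissue Treg and ST2-associated genes, which include Il1rl1, Gata3, Il10 and Ccr8, differed between genotypes in the step from DN to DP, with a median difference of -0.707 log2 units (13 of 14 negative). It was -0.783 without Fl DN 7876, whose Itgae level of 117 CPM might reflect CD103-positive cells, -0.652 with genes detected as a covariate and -0.750 without the macrophage-rich WT DP 7934 and Fl DP 7863, so none of these accounts for it alone. The mean DP minus DN score of the 13 genes other than Il1rl1 (median difference -0.679) was 0.974 ± 0.454 (SD, n = 5) in Fl and 1.66 ± 0.395 (n = 4) in WT, and within the sets of S above and up to 20 the genotype difference was -0.631 (SE 0.223), so the sets do not account for it. Of all splits of the 9 title numbers into 4 and 5, 6 gave a difference as large as the real -0.685 (exact p = 0.0476; highest other 0.886), and the list was picked for its difference, so chance stays open. Summed over the 14 genes, DN libraries held 2017 ± 261 CPM (SD) in Fl against 1698 ± 143 CPM in WT. DP libraries held 3902 ± 434 against 5057 ± 347 CPM. These sums include Il1rl1, the targeted gene, at 358 against 988 CPM in DP and 77.8 against 127 CPM in DN. Much of the lower DP sum in Fl is thus Il1rl1 itself. With Il1rl1 included, the smaller step goes with a higher DN level as well as a lower DP level in Fl. The sums were not taken without it. The data allow a smaller rise from DN to DP when ST2 is targeted, but do not place it in DP cells alone. Camera with an estimated correlation gave adjusted p = 0.108 for the list (0.0212 with the block). The preset test gave 0.071 without the 5 libraries of lowest total, and the list includes the targeted gene.

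Nfkbia and Nfkbiz were lower in Fl, by a mean of -0.930 log2 units over the populations. The immediate early and heat shock genes did not fall with them, with a median change of 0.0585 (SE 0.136). That SE is taken across the 20 genes, which are not independent, and measures no spread between mice. The test therefore cannot exclude a difference in handling stress. Without the title number 7876 the list passed upward in Fl (camera adjusted p = 0.0122, but 0.362 with an estimated correlation). An S number covariate (-0.913) or genes detected as a covariate (-0.915) left the fall of Nfkbia and Nfkbiz in place. Whether loss of signalling through Il1rl1 contributes was not decided. The fall was larger in DP, where Il1rl1 is most abundant, than in DN by a mean of -0.721 (mean SE 0.343, Nfkbia -0.58 ± 0.27, Nfkbiz -0.86 ± 0.42). Neither gene's difference passed over all genes. Nfkbia had been called in DP in the same libraries, which favours a larger fall there. Il1rl1 was lowest relative to WT in SP (24.7%). The falls of Nfkbia and Nfkbiz there were -0.74 ± 0.20 and -0.96 ± 0.32, against -1.12 ± 0.19 and -1.56 ± 0.30 in DP. The other 14 NF-kB targets decide nothing here (camera p = 0.84 with an estimated correlation, 9 negative). Chance was not excluded for the averaged comparison, since 5 of 56 splits of the title numbers gave as many genes as the real 8 (highest other 72).

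Macrophage and dendritic cell markers summed to 3721 CPM in WT DP 7934 (other WT DP libraries 343 to 535) and 5040 CPM in Fl DP 7863 (other Fl DP libraries 165 to 602), each far above its group. RNA or cells of macrophages in the sorted fraction are a candidate, which the gate on Foxp3, CD103 and KLRG1 would be meant to remove. Over 4-fold excess in both libraries held for 9 of 13 markers, under the 10 that the test asked for, so it is left open; Itgam, Emr1, Ctss and H2-Eb1 fell short. Lyz2 reached 1627 and 1583 CPM against a median of 5.23 in the other DP libraries (highest 70.2), and Chi3l3 676 and 2109 against 6.28 (highest 50.6). Csf1r had 118 and 78.9 CPM against a median of 0, but another DP library reached 73.6. H2-Aa, among the 9 markers, had 83.8 and 56.9 CPM, and another DP library reached 82.9. A like rise of every other cell type is excluded, as 0 of 6 other marker lists exceeded 4-fold in both.

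Other libraries stood apart from their groups in single measures. Genes with a count numbered 10235 in Fl SP 7833, against 11471 to 11900 in the other Fl SP libraries. Macrophage markers summed to 698 CPM in WT DN 7853, against 270 to 332. Endothelial markers summed to 90.4 CPM in Fl DP 8000, against 27.7 to 43.3. Erythrocyte markers summed to 13.8 CPM in Fl DN 7859, against 0 to 3.98. Il1rl1 was 240 CPM in WT DN 7853, against 80.9 to 105, and 182 CPM in Fl DN 8000, against 41.5 to 64.9.

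Another 5 population steps, of 4 other lists, differed between genotypes at the preset correlation. Of these lists, suppressive effectors share Fgl2, Il10 and Areg with the tissue Treg list and add no independent result. For SP against DN, the median differences were -1.14 for proliferation (28 negative; adjusted p = 5.48e-07, but 0.464 with an estimated correlation, and 0.0143 without WT SP 7955, where the median was -0.322) and -5.83 for CD8 T and NK cell markers, or -3.72 with bounds (adjusted p = 0.00958, but 0.279 with an estimated correlation, and 0.139 without the 5 libraries of lowest total). For DP against DN they were -0.616 for suppressive effectors (adjusted p = 0.037, but 0.161 with an estimated correlation, or 0.0212 with it in the blocked model, and 0.071 without the 5 libraries of lowest total) and -0.197 for glycolysis (adjusted p = 0.0287, but 0.299 with an estimated correlation, and 0.146 without Fl DN 7876). For DP against SP it was 0.703 for proliferation (adjusted p = 1.09e-05, but 0.793 with an estimated correlation, and 0.0502 without WT SP 7955, where the median was 0.163).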

How the results depend on the processing

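Every named gene kept its direction wherever it was called: of 2373 values for 105 results under other settings, 2053 kept direction and side of the threshold, 271 lost the call (161 of them on leaving out a library), 12 gained it and 0 reversed. The other 37 are changes of uncalled values. Leaving out Rn45s, the libraries of lowest total or WT DP 7934 and Fl DP 7863, the S number covariate, and the list tests without libraries, were chosen after seeing the data. No scaling moved the genes averaging 3 log2 CPM or more by a median above 0.1 in size (largest -0.0318). Changes of 1 log2 unit were mostly missed on simulated counts, above 8 CPM too (8.51% found for DP against DN in WT). The causes of the shifts below were not tested, except that fewer libraries were used where some were left out.

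Counts of genes are given in the order SP against DN, DP against DN and DP against SP within a genotype. DESeq2 called 9, 143 and 28 genes in WT, against 2, 50 and 1, and 39, 96 and 26 in Fl, against 1, 27 and 3. It called 8, 7 and 13 genes for Fl against WT in DN, SP and DP, against 0, 0 and 1, and 5, 7 and 5 for the genotype differences, against 0. With the replicate block, the paired counts became 115 for DP against DN in WT, and 13, 59 and 8 in Fl; with genes detected as a further covariate they were 102, and 11, 49 and 5. With the block 3 genes passed for SP against DN in WT, against 2, and 1 for DP against SP in WT, as before. Voom quality weights gave 93 for DP against DN and 3 for DP against SP in WT, 5 for DP against SP in Fl, and 1 and 7 for Fl against WT in DN and DP; with the random block they gave 1 on average, against 8. Without the libraries of lowest total the counts were 1, 23 and 0 in WT, 7 for DP against DN in Fl and 3 on average. Without WT DP 7934 and Fl DP 7863 they were 0 for DP against SP in WT, 16 for DP against DN and 1 for DP against SP in Fl, 0 for Fl against WT in DP and 3 on average. With only the libraries compared they were 1 for SP against DN in WT, 0 and 17 for SP and DP against DN in Fl, and 0 for Fl against WT in DP. With no filter on low counts they were 5 and 7 for DP against SP in WT and Fl, and 1 and 3 for Fl against WT in SP and DP. On the normalized table limma-trend gave 8 for DP against SP in WT, and 2 and 0 for SP against DN and DP against SP in Fl. The S number covariate gave 41 for DP against DN in Fl and 17 on average, and genes detected gave 1 for DP against SP in Fl. Of 73 list tests that passed at the preset correlation, 26 passed with an estimated correlation and 25 held at the preset correlation on leaving out each library or title number; with an estimated correlation 13 of the 26 held. Another 44 list tests passed without some library or title number, 1 of them with an estimated correlation (Tfr genes, DP against SP in Fl).

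Leaving out each library in turn gave 1 to 3, 27 to 44 and 0 to 2 genes in WT, and 1 to 4, 15 to 22 and 1 to 6 in Fl. It gave 0 to 0, 0 to 1 and 0 to 1 for Fl against WT in DN, SP and DP, 0 to 0 for each genotype difference, and 2 to 13 on average when leaving out each title number.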

Other observations

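Among the tests in this part, those without libraries or title numbers and those by S number were chosen after seeing results, and the others before. Proliferation genes differed between populations and genotypes at the preset correlation only, and much of this rested on single libraries. From DN to SP they were higher in WT (23 of 31 positive, median 0.26; adjusted p = 0.00923, but 0.413 with an estimated correlation) and lower in Fl (24 negative, median -0.68, or -0.73 with bounds; adjusted p = 0.000489, but 0.295 with an estimated correlation). The WT median turned to -0.18 without WT SP 7955, at 2396 CPM (adjusted p = 0.672), and to -0.11 without WT DN 7853 (0.257). The Fl median was -0.19 without Fl DN 7876, at 2341 CPM (0.242). Mki67 changed by 1.61 ± 0.67 in WT and -0.44 ± 0.56 in Fl, and Top2a by 0.96 ± 0.66 and -0.59 ± 0.56. From SP to DP they were lower in WT (21 negative, median -0.41, or -0.42 with bounds; adjusted p = 0.0129, but 0.506 with an estimated correlation) and higher in Fl (24 positive, median 0.43; adjusted p = 0.00467, but 0.491 with an estimated correlation, and 0.163 without WT DP 7934 and Fl DP 7863), where the WT median was 0.07 without WT SP 7955 (0.806). In SP cells 27 of 31 were lower in Fl than in WT (median -1.04, or -1.15 with bounds; adjusted p = 1.53e-10, but 0.243 with an estimated correlation, and 0.0015 without WT SP 7955, with a median of -0.58), with Mki67 at -1.85 ± 0.62 and Top2a at -1.57 ± 0.63. On average over the populations 27 were lower (median -0.62; adjusted p = 0.00165, but 0.397 with an estimated correlation, but with medians of -0.08 without the number 7955 and -0.20 without 8000, where it did not pass at 0.234 and 0.145), and no member passed over all genes in limma or edgeR. The summed level was 1612 ± 687 CPM (SD, n = 3) in WT SP and 976 ± 230 CPM (n = 5) in Fl SP. The 4 WT DN libraries had 1129 ± 393 CPM and the 5 Fl DN libraries 1272 ± 639 CPM. DP against DN did not pass in WT (adjusted p = 0.948) or Fl (0.529, but 0.0257 without Fl DP 7863 and 0.0333 without Fl DN 8000, where an estimated correlation gave 0.562 and 0.497), nor did Fl against WT in DP (0.656, but 0.0449 without Fl DP 7863, where an estimated correlation gave 0.629) or the genotype difference in DP against DN (0.546).

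Interferon response genes were higher in Fl than in WT SP cells (15 of 18 positive, median 0.28; adjusted p = 0.0102, but 0.608 with an estimated correlation) and on average (14 positive, median 0.42; adjusted p = 0.0026, but 0.332 with an estimated correlation). Both were lost without the number 7863, the highest Fl library of each population (3240, 4045 and 3784 CPM in DN, SP and DP): without it the adjusted p was 0.337 in SP (median 0.05) and 0.789 on average (median 0.11). The averaged call was lost without 7934 or 7955 too (0.111 and 0.105). Irf7, a transcription factor of the interferon response, had an average change of 0.71 ± 0.31 (adjusted p = 0.669). They did not pass in DP against SP or DN in Fl (0.22 and 0.913), but did without Fl DP 7863 (0.000245 and 0.0257, lower in DP, with medians of -0.46 and -0.37). In DP cells of Fl against WT (0.0527) and from DN to DP in WT (0.098) they did not pass, except without the 5 libraries of lowest total (0.0215 and 0.0316) and without each of 6 and 2 single libraries (down to 0.00645 and 0.00231). None of these held with an estimated correlation (0.231 or more). Glycolysis genes were lower in SP than in DN cells of Fl mice (12 of 15 negative, median -0.16; adjusted p = 0.00524, but 0.199 with an estimated correlation, and 0.033 in the blocked model with an estimated correlation). They were lower in DP than in DN cells of Fl mice too (11 negative, median -0.13; adjusted p = 0.000714, but 0.113 with an estimated correlation, and 0.0203 in the blocked model with an estimated correlation). Without Fl DN 7876 neither passed (adjusted p = 0.204 and 0.0739). Pgk1, a kinase of glycolysis, had a change of -0.94 ± 0.22 from DN to SP in Fl and passed when adjusted over the list alone. Immediate early and heat shock genes were higher in SP than in DN cells of WT (adjusted p = 0.0498, but 0.413 with an estimated correlation) and of Fl (adjusted p = 0.00977, but 0.295 with an estimated correlation). From DN to DP they were higher in Fl (adjusted p = 0.00446, but 0.271 with an estimated correlation, and 0.198 without WT DP 7934 and Fl DP 7863). These 3 calls were lost without at least 1 library (adjusted p up to 0.348, 0.404 and 0.394). In WT that list did not pass (0.0516), except in the blocked model (0.00483) without the 5 libraries of lowest total (0.0256) and without WT DN 7934 or WT DP 7853 (down to 0.00918), and none held with an estimated correlation (0.0803 or more). Its member Zfp36, which promotes mRNA decay, rose by 1.32 ± 0.28 (adjusted p = 0.0239).

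Chemokine receptors and integrins moved both ways from DN to DP in WT (Ccr8 and Cxcr6 rose and Cxcr3 fell; adjusted p = 0.646), with 3 higher and 4 lower when adjusted over the list alone. The list did not pass in the other comparisons (0.238 to 0.957). Cholesterol and lipid genes (smallest adjusted p = 0.0834), Th17 genes (0.0764), neutrophil markers (0.284) and erythrocyte markers (0.26) did not pass in any comparison of all libraries. For Fl against WT in DP, cholesterol genes passed without WT DP 7934 and Fl DP 7863 (0.0462) or without the 5 libraries of lowest total (0.0497), and in neither case with an estimated correlation (0.366 and 0.283). Neutrophil markers summed to 42.1 to 56.2 CPM and erythrocyte markers to 0.869 to 4.38 CPM by group. For naive and central genes in DP of Fl against WT, the adjusted p was 0.0497 without the 5 libraries of lowest total, but 0.213 with an estimated correlation.

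Counts of genes were compared with those from other splits of the same libraries into groups of the same sizes. For DP against DN, as many genes came only from the real split in WT (1 of 35, real 50, highest other 0) and in Fl (1 of 100, real 27, highest other 1). No share under 1 in 35 was possible in WT. The other splits mix DN and DP libraries, so differences between the populations widen their spread and hold down their counts. The sort markers, which the gate fixes, are among the genes counted. The real count thus stood above every other split, but chance is not excluded by it. For DP against SP only the real split gave as many in WT (1 of 35, real 1, highest other 0) and in Fl (1 of 100, real 3, highest other 1). Leaving out 1 library brought those counts down to 0 and 1, so these splits decide nothing; the gene left in Fl, and the only one in WT, is the sort marker Klrg1. For SP against DN the count did not exclude chance in WT (2 of 35, real 2, highest other 3) or in Fl (6 of 100, real 1, highest other 1). Counts so small cannot tell the sort marker Itgae, called in both, from stray calls, so they do not bear on Itgae itself. Among splits that part as many pairs, 7 others in WT gave at most 3, 0 and 0 genes for SP against DN, DP against DN and DP against SP, and 13 others in Fl gave at most 0. Between genotypes chance was not excluded in DP (6 of 100, real 1, highest other 2). A real count of 0 is reached by every split, so the splits say nothing on DN (100 of 100, highest other 1), SP (56 of 56, highest other 2) or the genotype differences (56 of 56 each, with highest others of 2, 1 and 1).

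The averaged split with 72 genes put the numbers 7833, 7853, 7854 and 7859 on 1 side. These are the numbers with S above 20, which points to a structure of the libraries. All libraries of a title number lie on 1 side of 20, so this compares 4 numbers with 5. Between S above 20 and S up to 20, 101 genes passed in limma with the title number as a random block (72 higher above 20), and 160 in edgeR without it (83 higher). Each side holds both genotypes, and with S above 20 as a covariate 17 genes passed on average, among them all 8 named before.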
